A study of Mus musculus with 27 samples.

How the data were processed

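The series measured RNA of pools of mouse embryos in 27 libraries, 3 in each of 9 groups. Per the labels' protocols, polyadenylated RNA was amplified with a low-input kit for single cells and sequenced on an Illumina instrument. The deposited values are raw counts per gene, made by the authors with STAR 2.7.11a and featureCounts, per the submitters' processing notes, which also name Subread 2.0.6, MultiQC and Scanpy 1.8.2. The same notes name the builds mm10 and GRCh38 without a role for each. The annotation release, the strand setting and the handling of read pairs are not given in the sources used here. Each count file held 55367 gene rows and 2 rows for MERVL, a mouse endogenous retrovirus, and how the MERVL rows were counted is likewise not given in the sources used here. Of the gene symbols, 53292 were found in the reference list of gene names. The table of the whole series held the same counts as the sample files for 27 of 27 libraries.

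Library totals ran from 7557591 to 11988857 counts. Of the nonzero counts, 84.5% were even (83.3 to 85.9% per library), as would arise if each read of a pair were counted. Floors for genes at 0 cover counting error only and would then be too low. Replicates of a group were compared for duplicates, and over 27 pairs the chi-square per degree of freedom between replicates ran from 4.18 to 24.4. The share of counts in mitochondrially encoded genes, the genes detected and the MERVL rows were computed per library, on the counts as deposited and after thinning each library to 7557591 counts, and groups were compared with two-sided exact permutation tests.

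Groups were taken from the sample titles. Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, R 4.3.3) on the deposited counts, in 1 fit per family, after filterByExpr with a minimum count of 10, which kept 18299 genes in the inhibitor family and 19182 in the siRNA family. P values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Each treated group was compared with its control, TSA with SAHA, and siComb with each single injection. Mean CPM values are edgeR's, scaled by TMM, while CPM values of single libraries use the library totals, except for the targets of the siRNAs.

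Gene lists, 24 in all, covered developmental stages and lineages, chromatin regulators, stress, metabolism and markers of other cell types. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes and a prior count of 2, for lists with at least 3 genes tested. Lists were also tested with an estimated correlation, under which 7 of 56 list calls against a control held, and with fry. For genes at 0 in every library of a group, a fold was bounded by 3 counts over the group. List medians were computed a second time with such genes at their bound.

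The groups, tests, lists, other settings and the rule for naming genes were fixed before the data were examined. The rule named Ep300, Crebbp, Kat6a, Kat6b and MERVL-int in every comparison. It named the 6 rising and 6 falling genes (4 and 4 between treated groups) with the largest fold changes among those with adjusted p under 0.05, a mean of at least 10 CPM and groups that did not overlap, leaving out unnamed gene models. It further named up to 3 genes per list by adjusted p, or the most abundant member of a list with none. Not all genes that the rule allows were written out.

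Positions of the 4 acetyltransferase genes are those of GENCODE vM21 on GRCm38, which is the build the notes call mm10. Overlaps of calls were set beside those of independent lists of the same sizes. For comparisons sharing a control, they were also set beside 100 simulated draws of unchanged groups and a control. All of these were drawn from the mean of the real control group, and the real control libraries themselves were not part of the draws. Lengths of genes were taken from the exons in GENCODE vM21 and were found for 100% of the 77 ribosomal protein genes tested.

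Alternatives were scaling by DESeq2 size factors or by library size alone, DESeq2 1.42.0, limma-voom with sample weights, no filter or a filter of at least 5 CPM, a replicate block, a fit of just the groups compared or of all 27 libraries, a 2-fold threshold, the series-wide table and leaving out each library in turn. Halved counts, a fit without 4 libraries of the siRNA family that stood apart and the overlaps of SAHA and TSA with the siRNA family were added after seeing the data. The test was checked on simulated counts with known changes. For SAHA against Vehicle (15252 genes) it recovered 1 of 67 genes changed 1.5-fold, 26 of 67 (38.8%) changed 2-fold and 60 of 66 (90.9%) changed 4-fold, with 4 false calls among 91. For siP300 against siControl (16693 genes) it recovered 0 of 67, 20 of 67 (29.9%) and 60 of 66 (90.9%), with 3 false calls among 83. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used for the library measures and figures.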

Results

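The data were counts of polyadenylated RNA from mouse embryos grown in culture and collected as morulae, in pools of 15 to 20 embryos. The series concerns a microRNA and the epigenetic control of early development. Its 27 libraries formed 9 groups of 3. In the first family, embryos received an inhibitor at embryonic day 2.5: SAHA and TSA, which block histone deacetylases, or A485, which blocks the acetyltransferases p300 and CBP, with a Vehicle group as control. In the second family, embryos were injected at embryonic day 0.5 with siRNA: siP300, siKat6a, siKat6b or a group named siComb, with siControl as control. The labels do not say which siRNAs siComb held. The file headers gave doses of 500 nM for SAHA, 10 uM for A485 and 50 nM for TSA. Libraries held between 7557591 and 11988857 counts. The series text calls the 3 pools of a group biological replicates but does not say whether they were collected or prepared separately, so p-values here measure the spread between these samples, which may be technical.

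In what follows, levels in parentheses are means ± SD of CPM (counts scaled to a common library size, n = 3 libraries per group), with the treated group first, and "log2" is the edgeR log2 fold change ± SE or its median over a list. A gene "rose" or "fell" where the edgeR quasi-likelihood test gave a Benjamini-Hochberg adjusted p under 0.05. Gene groups are fixed lists tested with camera; where the call is lost with an estimated correlation between genes, that adjusted p follows. "Library size alone" means a fit without TMM scaling, and counts adjusted over the list alone are given where they differ from those over all genes. Genes of multicopy families, such as the 2-cell families, the histones and the ribosomal proteins, share sequence with near-identical copies, so their levels are uncertain, as are those of genes overlapping another gene on either strand. Counting errors alone set the floors given for genes at 0.

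The endogenous retrovirus MERVL, which is transcribed at the 2-cell stage and silenced afterwards, differed widely between libraries. Its internal region, MERVL-int, took 4517, 2181 and 4569 CPM in the SAHA libraries and 9742, 8393 and 9195 in the TSA libraries. The Vehicle libraries held 12.5, 14.3 and 244.6 CPM, so Vehicle 3 stood apart from its group. The A485 libraries held 8.50, 16.2 and 5.55. In the siRNA family the siControl libraries held 23.4, 32.8 and 21.2 and the siKat6a libraries 20.4, 28.3 and 44.3. The siP300 libraries held 151, 915 and 158, the siKat6b libraries 899, 35.0 and 946, and the siComb libraries 71.6, 990.2 and 61.8. A second MERVL row, MERVL_2A-int, stood at 147 ± 52.1 CPM with SAHA, 335 ± 28.1 with TSA, 10.1 ± 4.79 with A485 and 22.4 ± 3.23 with Vehicle (exact permutation p = 0.1 for each inhibitor, two-sided, the smallest that 3 libraries against 3 allow).

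**Figure D1:**
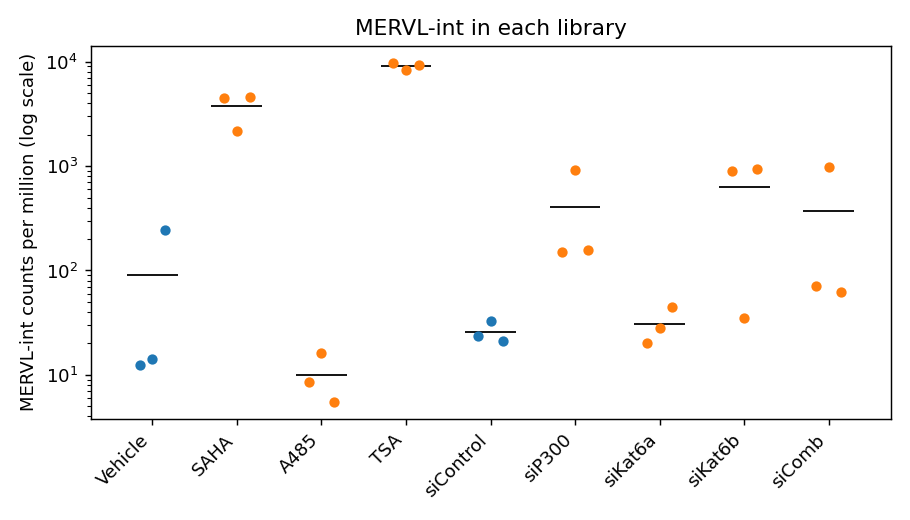
MERVL-int CPM (log axis) in each of the 27 libraries, by group. Points are libraries and lines are group means. All SAHA and TSA libraries lie above 2181 CPM, Vehicle 3 lies at 244.6, and siP300 2, siKat6b 1, siKat6b 3 and siComb 2 lie far above the other libraries of the siRNA family.

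Mitochondrially encoded genes took 1.07 ± 0.109% of counts in Vehicle, 1.95 ± 0.293% in SAHA, 2.51 ± 0.136% in A485 and 3.11 ± 0.548% in TSA. Their share was 2.27 ± 0.281% in siControl, 5.84 ± 1.05% in siP300, 5.14 ± 0.276% in siComb, 2.15 ± 0.241% in siKat6a and 2.15 ± 0.335% in siKat6b. Each inhibitor group, siP300 and siComb lay above its control in every library (exact permutation p = 0.1, the smallest possible). After thinning every library to the smallest total, genes with at least 10 counts numbered 13623 ± 110 in Vehicle, 15243 ± 93.9 in SAHA, 16177 ± 284 in TSA and 13082 ± 285 in A485. They numbered 14494 ± 50.6 in siControl, 16964 ± 471 in siP300, 16079 ± 389 in siComb, 15291 ± 446 in siKat6b and 14627 ± 242 in siKat6a.

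SAHA against Vehicle asked what blocking histone deacetylases for the last hours before the morula stage did to the embryos' RNA. Embryos given SAHA carried high levels of 2-cell stage RNA and lower levels of trophectoderm and pluripotency genes (the 2-cell call was lost with an estimated correlation, adjusted p = 0.35). MERVL-int stood at 3782 ± 1471 against 90.9 ± 134 CPM (log2 5.38 ± 0.96, or 8.18 without Vehicle 3; edgeR adjusted p = 7.30e-04). Of the 18299 genes tested, 6261 changed, 3695 higher and 2566 lower, and 4568 of them by at least 2-fold. Groups did not overlap for 54.2% of genes tested, where chance gives 10% in this and later comparisons.

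Of the 2-cell genes, 33 of 39 rose and 1 fell (34 and 1 adjusted over the list alone), with a median log2 fold change of 5.17, or 5.12 with the gene at 0 in Vehicle set at its bound (camera adjusted p = 1.64e-11, or adjusted p = 0.35 with an estimated correlation). Without Vehicle 3, 35 rose and the median was 10.1. Rising members included Tmem92 (314 ± 69.2 against 5.86 ± 5.36) and Zfp809 (275 ± 49.0 against 42.8 ± 4.44), a zinc finger protein that silences retroviruses. Of the histone genes, 19 of 26 rose and 1 fell (22 and 2 adjusted over the list alone), median log2 1.98 (camera adjusted p = 9.43e-06). The linker histone gene H1f0 (649 ± 174 against 57.9 ± 10.5) was among them. Of the germline genes kept silent by DNA methylation, 22 of 39 rose and 2 fell (24 and 3 adjusted over the list alone), median log2 1.41 (camera adjusted p = 4.27e-05, or adjusted p = 0.142 with an estimated correlation), as in Sycp1 (205 ± 15.0 against 47.8 ± 14.9), which encodes a synaptonemal complex protein,. Of the neuronal genes, 12 of 31 rose and 2 fell (13 and 2 adjusted over the list alone), median log2 0.93 (camera adjusted p = 0.0165, or adjusted p = 0.285 with an estimated correlation); without Vehicle 3 the camera adjusted p was 0.0552 (range over alternatives 0.0159 to 0.285). Bex2 (24.4 ± 5.91 against 0.374 ± 0.324) and Mapt (214 ± 21.4 against 87.2 ± 6.81), which encodes the microtubule protein tau, rose. Outside the lists, a large rise was in the growth factor gene Fgf7 (35.9 ± 6.35 against 0.126 ± 0.109).

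Of the trophectoderm genes, 27 of 43 fell and 2 rose (29 and 2 adjusted over the list alone), median log2 -1.40 (camera adjusted p = 3.19e-09). Id2 (91.1 ± 5.73 against 518 ± 59.3) fell, while Cdh3 (24.8 ± 2.09 against 3.15 ± 0.788), which encodes P-cadherin, rose. Of the pluripotency and epiblast genes, 19 of 33 fell and 1 rose (20 and 1 adjusted over the list alone), median log2 -1.02 (camera adjusted p = 4.27e-05). Among them was Tfcp2l1 (58.3 ± 11.6 against 211 ± 6.23). Of the histone acetyltransferases and cofactors, 14 of 46 fell and 1 rose, median log2 -0.40 (camera adjusted p = 5.48e-04). Meaf6 (26.6 ± 4.01 against 68.8 ± 4.38), a subunit of MYST acetyltransferase complexes, fell and the coactivator gene Ncoa2 (116 ± 12.7 against 22.9 ± 3.22) rose. The CBP gene Crebbp (63.2 ± 0.522 against 128 ± 7.70 CPM, log2 -1.02 ± 0.18) fell, and so did Kat6b (52.5 ± 5.27 against 90.6 ± 16.4 CPM, log2 -0.79 ± 0.22) (edgeR adjusted p = 0.0132; 0.0677 without Vehicle 1 and 0.0581 without SAHA 3, range 0.00146 to 0.0677). Ep300 (16.2 ± 0.740 against 22.8 ± 1.31 CPM, log2 -0.49 ± 0.23) and Kat6a (11.4 ± 1.79 against 14.5 ± 2.15 CPM, log2 -0.34 ± 0.28) did not pass (edgeR adjusted p = 0.114 and 0.373), except Ep300 with just these groups in the fit (log2 -0.46, 0.0427; range 0.0427 to 0.265). Of the DNA methylation and Polycomb genes, 13 of 37 fell and 2 rose, median log2 -0.25 (camera adjusted p = 0.00636, or adjusted p = 0.141 with an estimated correlation). Among them was Tet2 (24.8 ± 3.44 against 126 ± 4.02), a methylcytosine dioxygenase. A large fall elsewhere was in Serpinb9b (1.88 ± 0.594 against 103 ± 23.9).

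For the other lists with SAHA, the camera adjusted p lay between 0.147 and 0.975. Members that rose and fell numbered, with differing counts adjusted over the list alone in brackets, primitive endoderm 5 and 5 of 24, maternal oocyte 3 and 3 of 31 [2 and 3], deacetylase and corepressor 10 and 10 of 41, p53 target 4 and 5 of 35, integrated stress response 4 and 6 of 39 [3 and 5], heat shock 4 and 8 of 26 [4 and 9], YAP TEAD target 6 and 3 of 30, cholesterol synthesis 6 and 2 of 23, glycolysis 10 and 6 of 24 [11 and 6], ribosomal protein 2 and 0 of 76 [0 and 0], respiratory chain 12 and 8 of 71 [11 and 6], imprinted 5 and 5 of 30 [5 and 6], cumulus and granulosa 1 and 2 of 8, oviduct and stromal 0 and 0 of 6, blood and immune 5 and 1 of 8 and Y-linked 0 and 0 of 4. Among these, Sqle (79.4 ± 15.6 against 17.6 ± 2.71), an enzyme of cholesterol synthesis, and Ldhb (35.1 ± 12.9 against 1.85 ± 0.600), a lactate dehydrogenase, rose, and the hexokinase gene Hk2 (10.9 ± 4.11 against 98.3 ± 21.6) fell. Without Vehicle 3, numbers moved for cholesterol synthesis genes (3 rose, 0 fell), respiratory chain genes (7 rose, 2 fell), glycolysis genes (9 rose, 2 fell) and imprinted genes (5 rose, 3 fell).

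A485 against Vehicle asked what blocking p300 and CBP did over the same window. Embryos given A485 had lost much of the RNA of pluripotency, trophectoderm and primitive endoderm genes, while respiratory chain and glycolysis genes were higher. The last-named calls were lost with an estimated correlation (adjusted p = 0.449 and 0.533). Of the 18299 genes tested, 8328 changed, 3907 higher and 4421 lower, 2740 and 3538 of them by at least 2-fold. The majority turned, from 46.9% higher, with the filter at 5 CPM (51.1%) and without A485 1 (50.6%). Groups did not overlap for 52.7% of genes.

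Of the pluripotency and epiblast genes, 31 of 33 fell and 0 rose (32 and 0 adjusted over the list alone), median log2 -3.83 (camera adjusted p = 1.77e-15). With genes at 0 set at their bound the median was -3.69. Dppa3 (127 ± 49.6 against 6652 ± 751), also called Stella, and Tfcp2l1 (14.7 ± 2.20 against 211 ± 6.23) fell, and Tdgf1 went from 74.8 ± 29.8 CPM to 0 in every A485 library, 882-fold lower against a floor of 3 counts over the group. Of the trophectoderm genes, 29 of 43 fell and 6 rose (30 and 6 adjusted over the list alone), median log2 -2.52 (camera adjusted p = 1.51e-07). Of the primitive endoderm genes, 16 of 24 fell and 2 rose (17 and 2 adjusted over the list alone), median log2 -2.67 (camera adjusted p = 5.11e-05). Among them was the transcription factor gene Gata6 (1.17 ± 0.936 against 119 ± 17.4).

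MERVL-int was lower with A485 (9.62 ± 5.25 against 90.9 ± 134 CPM, log2 -3.24 ± 0.89; edgeR adjusted p = 0.00862). Without Vehicle 3 its log2 was -0.48 (edgeR adjusted p = 0.324), with limma-voom -1.97 (adjusted p = 0.2265) and with a replicate block -2.44 (adjusted p = 0.0558, range 2.92e-74 to 0.324). Of the 2-cell genes, 33 of 39 fell and 0 rose (34 and 0 adjusted over the list alone), with a median of -5.40, or -5.02 with genes at 0 at their bound (camera adjusted p = 0.00176, or adjusted p = 0.817 with an estimated correlation). Without Vehicle 3, the list median was -0.11, the camera adjusted p 0.326 (range 6.71e-06 to 0.817), and 9 of the 33 still fell. Pramel7 (0.450 ± 0.0794 against 181 ± 13.7) and Eif1ad (59.9 ± 8.87 against 214 ± 13.6) fell.

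Respiratory chain genes were higher with A485. Of these genes, 40 of 71 rose and 8 fell (40 and 10 adjusted over the list alone), median log2 0.51 (camera adjusted p = 1.62e-05, or adjusted p = 0.449 with an estimated correlation). Among them was the complex I subunit Ndufa4 (1239.8 ± 53.1 against 374 ± 18.2). Of the glycolysis genes, 12 of 24 rose and 2 fell (13 and 2 adjusted over the list alone), median log2 0.64 (camera adjusted p = 0.0183, or adjusted p = 0.533 with an estimated correlation). The lactate dehydrogenase gene Ldha (338 ± 192 against 34.5 ± 4.41) and the phosphoglycerate kinase gene Pgk1 (223 ± 73.6 against 58.7 ± 2.747) rose and Hk2 (7.80 ± 2.44 against 98.3 ± 21.6) fell. Of the neuronal genes, 11 of 31 rose and 3 fell, with a median of 1.17, or 1.08 at the bound (camera adjusted p = 0.0415, or adjusted p = 0.533 with an estimated correlation). That call was lost without A485 1 (camera adjusted p = 0.171), without A485 3 (0.0540) and with library size alone (0.0525; range 0.0108 to 0.533). Bex2 (16.8 ± 7.96 against 0.374 ± 0.324) and the kinesin gene Kif5c (24.7 ± 11.8 against 2.12 ± 0.737) rose. The gene of p300 itself, Ep300 (53.8 ± 17.03 against 22.8 ± 1.31 CPM, log2 1.24 ± 0.23), rose, Kat6b (30.3 ± 9.72 against 90.6 ± 16.4 CPM, log2 -1.58 ± 0.22) fell, and Crebbp (157 ± 38.5 against 128 ± 7.70 CPM, log2 0.29 ± 0.18) and Kat6a (11.9 ± 4.96 against 14.5 ± 2.15 CPM, log2 -0.28 ± 0.28) did not pass (edgeR adjusted p = 0.196 and 0.445). The stress-induced transcription factor gene Atf3 (89.8 ± 23.6 against 0.363 ± 0.478) rose. The transcription factor gene Spic (0.173 ± 0.181 against 277 ± 75.1) fell.

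The other 17 lists did not pass with A485 (camera adjusted p from 0.104 to 0.978). The acetyltransferase gene Kat2b (41.0 ± 6.98 against 4.95 ± 0.557) and the imprinted gene Impact (319.5 ± 60.04 against 39.6 ± 12.2) rose. The p53 target Tigar (17.5 ± 2.42 against 315 ± 28.1) and the serine synthesis gene Phgdh (22.8 ± 4.73 against 195 ± 58.8) fell.

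TSA against Vehicle put a second deacetylase inhibitor to the same test. TSA-treated embryos also carried high levels of 2-cell stage RNA, with lower trophectoderm and pluripotency genes and higher histone, germline and neuronal genes. With an estimated correlation 0 of the 8 list calls passed (adjusted p from 0.0598 to 0.403). MERVL-int stood at 9592 ± 645 against 90.9 ± 134 CPM (log2 6.72 ± 1.02, or 9.52 without Vehicle 3; edgeR adjusted p = 7.29e-05). Of the 18299 genes tested, 10641 changed, 5782 higher and 4859 lower, 5096 and 3441 of them by at least 2-fold. Groups did not overlap for 68.0% of genes.

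Of the 2-cell genes, 36 of 39 rose and 2 fell, median log2 6.65 (camera adjusted p = 1.60e-08, or adjusted p = 0.403 with an estimated correlation). Without Vehicle 3 the median was 11.5. Zfp809 (478 ± 69.6 against 42.8 ± 4.44) and Ubtfl1 (218 ± 18.8 against 13.7 ± 1.79) rose, and Pramel7 (7.41 ± 0.449 against 181 ± 13.7) fell. Duxf3, the mouse Dux gene, an activator of MERVL and of 2-cell genes, went from 0 in every Vehicle library to 24.9 ± 10.5 CPM, 268-fold higher against a floor of 3 counts over the group. Of the histone genes, 22 of 26 rose and 2 fell, median log2 1.60 (camera adjusted p = 4.49e-04, or adjusted p = 0.101 with an estimated correlation). H1f0 (423 ± 154 against 57.9 ± 10.5) was among them. Of the germline genes, 28 of 39 rose and 4 fell (30 and 6 adjusted over the list alone), median log2 2.37 (camera adjusted p = 7.72e-05, or adjusted p = 0.141 with an estimated correlation). Among them was Tex11 (46.8 ± 2.56 against 1.64 ± 0.667). Of the neuronal genes, 19 of 31 rose and 1 fell (21 and 1 adjusted over the list alone), median log2 1.96 (camera adjusted p = 2.17e-04, or adjusted p = 0.101 with an estimated correlation). Among them was Mapt (340.1 ± 12.8 against 87.2 ± 6.81).

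Of the trophectoderm genes, 29 of 43 fell and 5 rose (29 and 6 adjusted over the list alone), median log2 -1.88 (camera adjusted p = 1.10e-06, or adjusted p = 0.0598 with an estimated correlation). The transcription factor gene Gata3 (5.54 ± 0.954 against 312 ± 20.4) and the keratin gene Krt8 (85.3 ± 16.3 against 931 ± 24.1) fell. Of the pluripotency and epiblast genes, 24 of 33 fell and 3 rose, median log2 -1.80 (camera adjusted p = 4.97e-05, or adjusted p = 0.0598 with an estimated correlation). Among them was Nanog (11.1 ± 2.71 against 165 ± 47.2). Of the acetyltransferases and cofactors, 21 of 46 fell and 6 rose, median log2 -0.30 (camera adjusted p = 0.0176, or adjusted p = 0.101 with an estimated correlation). Tada1 (8.01 ± 2.68 against 105 ± 7.22), a subunit of the SAGA complex, Crebbp (34.5 ± 4.97 against 128 ± 7.70 CPM, log2 -1.89 ± 0.19) and Kat6b (20.4 ± 0.680 against 90.6 ± 16.4 CPM, log2 -2.15 ± 0.23) fell and Ncoa2 (163 ± 23.2 against 22.9 ± 3.22) rose. Ep300 (17.8 ± 2.58 against 22.8 ± 1.31 CPM, log2 -0.36 ± 0.23) and Kat6a (14.8 ± 0.803 against 14.5 ± 2.15 CPM, log2 0.034 ± 0.28) did not pass (edgeR adjusted p = 0.193 and 0.928). Of the DNA methylation and Polycomb genes, 17 of 37 fell and 4 rose, median log2 -0.81 (camera adjusted p = 0.0176, or adjusted p = 0.141 with an estimated correlation). Among them was Tet2 (6.34 ± 2.38 against 126 ± 4.02). Serpinb9b (0.269 ± 0.273 against 103 ± 23.9) fell too.

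The other 16 lists did not pass with TSA (camera adjusted p from 0.0736 to 0.987). Of the blood and immune cell markers, 6 of 8 rose and 1 fell (6 and 2 adjusted over the list alone), median log2 2.42 (camera adjusted p = 0.114). Of the 76 ribosomal protein genes, 14 fell and 2 rose (3 and 1 adjusted over the list alone). Those numbers were 23 and 2 with library size alone and 8 and 2 without Vehicle 3. The cholesterol synthesis gene Sqle (142 ± 14.5 against 17.6 ± 2.71) and the glycolysis gene Ldhb (142 ± 37.1 against 1.85 ± 0.600) rose. Gata6 (5.20 ± 1.93 against 119 ± 17.4) and Hk2 (9.74 ± 2.54 against 98.3 ± 21.6) fell.

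TSA and SAHA are both hydroxamates and were given at different doses, 50 nM and 500 nM, so their responses were compared side by side and not at matched doses. TSA-treated embryos differed from SAHA-treated ones at 3983 genes (1792 higher and 2191 lower with TSA), 2442 of them by at least 2-fold. The count was 2420 without SAHA 2 and 2601 without TSA 1. The majority direction was not stable: 44.99% were higher with TSA, and 37.4% with library size alone. Above 50% were DESeq2 and its size factors (56.9% each), limma-voom (55.7%), halved counts (54.2%), just these groups (52.3%) and the filter at 5 CPM (51.97%). Gpr50 (49.6 ± 9.14 against 3.19 ± 0.950) was higher with TSA. Pramel6 (16.4 ± 7.09 against 288 ± 50.3) was lower. Crebbp (34.5 ± 4.97 against 63.2 ± 0.522 CPM, log2 -0.87 ± 0.18) was lower with TSA (95% interval of log2 -1.27 to -0.48; edgeR adjusted p = 0.00442), as was Kat6b (20.4 ± 0.680 against 52.5 ± 5.27 CPM, log2 -1.36 ± 0.23) (-1.85 to -0.87; adjusted p = 0.00118). The compounds were not shown to differ in Ep300 (17.8 ± 2.58 against 16.2 ± 0.740 CPM, log2 0.13 ± 0.23), with an interval of -0.37 to 0.62, in Kat6a (14.8 ± 0.803 against 11.4 ± 1.79 CPM, log2 0.38 ± 0.29), with an interval of -0.23 to 0.99, or in MERVL-int (9592 ± 645 against 3782 ± 1471 CPM, log2 1.34 ± 0.81), with an interval of -0.39 to 3.08 (edgeR adjusted p = 0.724, 0.362 and 0.25). For MERVL-int the difference passed with limma-voom (adjusted p = 0.0174) and with just these groups in the fit (0.00496; range 9.75e-14 to 0.488).

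Cholesterol synthesis genes were higher with TSA than with SAHA: 12 of 23 rose and 0 fell (14 and 0 adjusted over the list alone), median log2 0.69 (camera adjusted p = 0.00294, or adjusted p = 0.104 with an estimated correlation). Of the neuronal genes, 9 of 31 rose and 0 fell (12 and 0 adjusted over the list alone), median log2 1.03 (camera adjusted p = 1.68e-04, or adjusted p = 0.15 with an estimated correlation). Of the germline genes, 11 of 39 rose and 2 fell (12 and 3 adjusted over the list alone), median log2 0.71 (camera adjusted p = 0.00589, or adjusted p = 0.355 with an estimated correlation). Of the 2-cell genes, 5 of 39 rose and 2 fell (2 and 2 adjusted over the list alone), median log2 1.35 (camera adjusted p = 0.0141, or adjusted p = 0.726 with an estimated correlation). Of the maternal oocyte transcripts, 6 of 31 rose and 3 fell (7 and 3 adjusted over the list alone), median log2 0.79 (camera adjusted p = 0.0361, or adjusted p = 0.181 with an estimated correlation). Lower with TSA were trophectoderm genes, of which 15 of 43 fell and 5 rose (18 and 6 adjusted over the list alone), median log2 -0.38 (camera adjusted p = 0.00861, or adjusted p = 0.224 with an estimated correlation). So were pluripotency genes, of which 11 of 33 fell and 0 rose (13 and 2 adjusted over the list alone), median log2 -0.71 (camera adjusted p = 0.00861, or adjusted p = 0.196 with an estimated correlation). Of the ribosomal protein genes, 9 of 76 fell and 1 rose (2 and 0 adjusted over the list alone), median log2 -0.24 (camera adjusted p = 4.74e-04, or adjusted p = 0.726 with an estimated correlation). Of the respiratory chain genes, 15 of 71 fell and 2 rose (17 and 2 adjusted over the list alone), median log2 -0.17 (camera adjusted p = 0.00543, or adjusted p = 0.549 with an estimated correlation). The other 15 lists did not pass (camera adjusted p from 0.0798 to 0.8).

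SAHA and TSA changed 5732 genes in the same direction and 19 in opposite directions, against 1168 higher in both, 681 lower in both and 1792 opposite for independent lists of those sizes. Across the 18299 genes the log2 fold changes of SAHA and TSA correlated at r = 0.918 (covariance 4.21). Unchanged groups and a control, all simulated from the Vehicle mean, gave r = 0.499 and covariance 0.106. SAHA and A485 shared 2256 changes in direction and 1035 were opposite (789, 620 and 1441 for independent lists; r = 0.0921, covariance 0.356). A485 and TSA shared 3485 and 1704 were opposite (1235, 1174 and 2434; r = 0.0992, covariance 0.519). Simulated unchanged groups shared 0.02 calls on average in 100 draws. These correlations run across genes, which are not independent replicates, and part of each excess may come from the shared Vehicle libraries, which are too few to split.

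In the siRNA family the targeted transcripts were measured first. Ep300 (chromosome 15, 81585351 to 81652077, plus strand, GRCm38) stood at 24.0, 24.9 and 30.6 CPM in the siControl libraries and at 17.9, 12.2 and 28.8 CPM in those labelled siP300 (19.6 ± 8.43 against 26.5 ± 3.58 CPM, log2 -0.43 ± 0.29; edgeR adjusted p = 0.259). Without siP300 3 it was -0.82 on the log2 scale (adjusted p = 0.0453; range 0.0452 to 0.885). Ep300 mRNA thus did not check the siP300 label, and directions below are those of libraries labelled siP300. Kat6a (chromosome 8, 22859535 to 22943259, plus strand) stood at 19.17, 16.7 and 17.4 CPM in siControl and at 14.1, 11.1 and 13.5 CPM in siKat6a (12.9 ± 1.58 against 17.7 ± 1.29 CPM, log2 -0.46 ± 0.20; edgeR adjusted p = 1). Kat6b (chromosome 14, 21481434 to 21672478, plus strand) stood at 106, 118 and 121 CPM in siControl and at 70.4, 83.2 and 80.8 CPM in siKat6b (78.1 ± 6.79 against 115 ± 7.90 CPM, log2 -0.56 ± 0.27; edgeR adjusted p = 0.495). Each siKat6a and siKat6b library thus lay below every siControl library for its target, short of the threshold over 19182 genes. Positions are those of the protein-coding genes in GENCODE vM21; Crebbp lies on chromosome 16, 4081328 to 4213997, minus strand.

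In the siComb libraries Kat6a stood at 12.4, 9.93 and 11.9 CPM (11.4 ± 1.29 against 17.7 ± 1.29 CPM, log2 -0.64 ± 0.20; edgeR adjusted p = 0.0219). That call was lost without siControl 1 (adjusted p = 0.0813), without siComb 2 (0.0854), without the 4 libraries that stood apart (0.109), without a filter on low counts (0.189) and with library size alone (log2 -0.37, 0.195; range 0.0153 to 0.195). Kat6b stood at 53.9, 32.6 and 82.7 CPM (56.4 ± 25.1 against 115 ± 7.90 CPM, log2 -1.03 ± 0.28; edgeR adjusted p = 0.00817). Ep300 stood at 25.3, 15.4 and 31.2 CPM (24.0 ± 8.00 against 26.5 ± 3.58 CPM, log2 -0.15 ± 0.29; edgeR adjusted p = 0.722). Crebbp (183 ± 8.13 against 149 ± 5.19 CPM, log2 0.30 ± 0.16) did not pass (edgeR adjusted p = 0.161) except with library size alone (log2 0.57, 0.0177; range 0.0177 to 0.314).

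**Figure D2:**
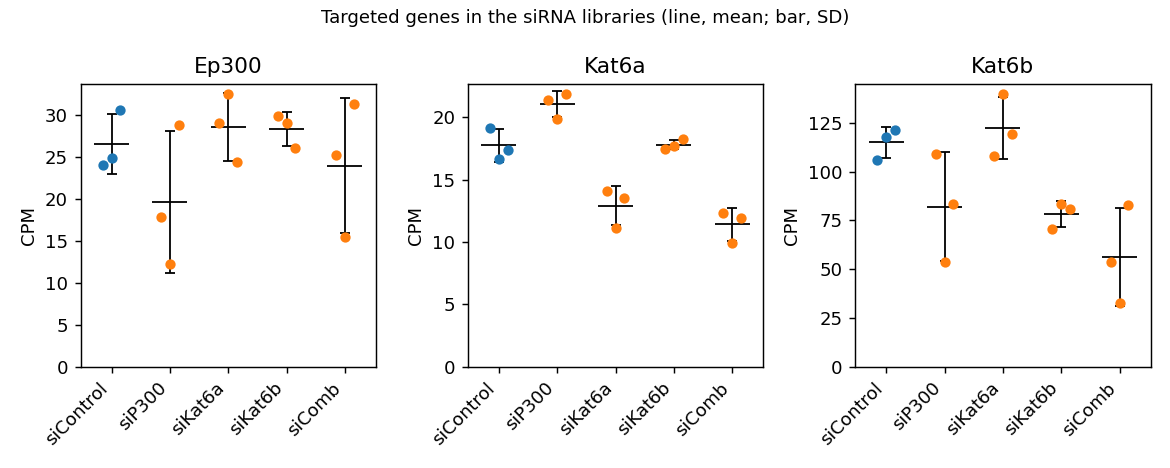
CPM of Ep300, Kat6a and Kat6b in the 15 libraries of the siRNA family. Points are libraries, lines are group means and bars are SD (n = 3). Ep300 in the siP300 libraries spans 12.2 to 28.8 CPM and overlaps siControl; Kat6b in siKat6b and Kat6a in siKat6a lie below siControl.

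In embryos labelled siP300, ribosomal protein and respiratory chain genes were lower and p53 target, imprinted and neuronal genes and markers of blood and cumulus cells were higher than in siControl. With an estimated correlation 0 of the 12 list calls passed (adjusted p from 0.0528 to 0.703). Of the 19182 genes tested, 6789 changed, 3787 higher and 3002 lower, 3140 and 1575 of them by at least 2-fold. Groups did not overlap for 48.0% of genes. Under library size alone, the median over all genes moved by 0.32 on the log2 scale and 76.9% of calls were higher, against 55.8%. The changes below are relative to the median gene.

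Of the ribosomal protein genes, 69 of 77 fell and 0 rose (73 and 0 adjusted over the list alone), median log2 -0.97 (camera adjusted p = 1.41e-22, or adjusted p = 0.225 with an estimated correlation). With library size alone 60 fell, with a median of -0.66. Rpl26 (697 ± 121 against 2064 ± 336) fell. Of the respiratory chain genes, 37 of 71 fell and 2 rose (42 and 2 adjusted over the list alone), median log2 -0.49 (camera adjusted p = 4.20e-09, or adjusted p = 0.352 with an estimated correlation). Under library size alone 19 fell and 2 rose, with a median of -0.17. Cox5a (649 ± 38.4 against 1392 ± 95.6), a cytochrome c oxidase subunit, and Ndufb5 (137 ± 15.3 against 280.5 ± 37.8) fell, while the mitochondrially encoded share was higher in every siP300 library. Of the glycolysis genes, 10 of 24 rose and 2 fell (11 and 2 adjusted over the list alone), median log2 0.79 (camera adjusted p = 0.00899, or adjusted p = 0.225 with an estimated correlation). Ldhb (176 ± 48.4 against 4.11 ± 1.14) rose and Hk2 (9.21 ± 1.47 against 46.9 ± 7.13) fell. Of the p53 targets, 20 of 37 rose and 1 fell (21 and 1 adjusted over the list alone), median log2 0.96 (camera adjusted p = 2.75e-05, or adjusted p = 0.225 with an estimated correlation). Among them was Mdm2 (438 ± 70.2 against 83.0 ± 2.62), the ubiquitin ligase of p53.

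Of the neuronal genes, 25 of 35 rose and 1 fell (26 and 1 adjusted over the list alone), median log2 2.42 (camera adjusted p = 6.35e-08, or adjusted p = 0.0528 with an estimated correlation). Uchl1 (220.0 ± 24.0 against 36.2 ± 12.5) was among them. Of the imprinted genes, 16 of 33 rose and 3 fell (17 and 3 adjusted over the list alone), median log2 0.77 (camera adjusted p = 0.00862, or adjusted p = 0.225 with an estimated correlation). Cdkn1c (59.5 ± 6.40 against 3.00 ± 1.15), a cyclin-dependent kinase inhibitor, and Impact (173 ± 28.9 against 34.6 ± 2.22) rose and Slc38a4 (10.2 ± 1.19 against 52.7 ± 3.91) fell. Of the blood and immune cell markers, 6 of 10 rose and 0 fell, median log2 2.32 (camera adjusted p = 6.16e-04, or adjusted p = 0.16 with an estimated correlation). Among them were Cd68 (37.7 ± 13.2 against 3.78 ± 0.2003), a macrophage marker, and Cd74 (81.7 ± 34.0 against 9.46 ± 4.40), the invariant chain. Of the cumulus and granulosa cell markers, 5 of 11 rose and 0 fell, median log2 1.73 (camera adjusted p = 0.00622, or adjusted p = 0.225 with an estimated correlation). Among them was the steroidogenic enzyme gene Cyp11a1 (8.86 ± 4.16 against 0.738 ± 0.199).

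Of the trophectoderm genes, 25 of 43 fell and 7 rose (25 and 9 adjusted over the list alone), median log2 -0.65 (camera adjusted p = 6.16e-04, or adjusted p = 0.225 with an estimated correlation). Among them was Id2 (107 ± 25.5 against 503 ± 40.2). With library size alone 16 fell and 9 rose. Of the pluripotency and epiblast genes, 16 of 35 fell and 2 rose (17 and 2 adjusted over the list alone), median log2 -0.62 (camera adjusted p = 1.62e-04, or adjusted p = 0.225 with an estimated correlation). Under library size alone 12 fell and 3 rose. Of the DNA methylation and Polycomb genes, 11 of 37 fell and 3 rose (12 and 3 adjusted over the list alone), median log2 -0.054 (camera adjusted p = 0.0408, or adjusted p = 0.503 with an estimated correlation). Among them was Dnmt3b (14.4 ± 5.11 against 65.2 ± 3.76). That list's median was 0.26 with library size alone (camera adjusted p = 0.0727), and the call was lost without siControl 3 (0.0583), siP300 2 (0.0855) or siP300 3 (0.0510) or the 4 libraries that stood apart (0.0598; range 0.00552 to 0.503). Of the 2-cell genes, 18 of 32 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 4.80, or 4.33 with genes at 0 at their bound (camera adjusted p = 0.00622, or adjusted p = 0.703 with an estimated correlation). Without siP300 2 the camera adjusted p was 0.170 (range 7.56e-05 to 0.703). MERVL-int (377 ± 424 against 28.5 ± 6.36 CPM, log2 3.73 ± 1.12) rose (edgeR adjusted p = 0.0167), but not without siControl 1 (0.0633), siControl 3 (0.0624) or siP300 2 (log2 2.24, 0.1005; range 3.17e-59 to 0.101).

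The other 12 lists did not pass with siP300 (camera adjusted p from 0.144 to 0.987). The stress gene Hmox1 (275 ± 80.3 against 29.3 ± 1.47), which encodes heme oxygenase, and the germline gene Taf7l (178 ± 38.3 against 1.796 ± 1.28) rose. The oocyte gene Tcl1 (1.47 ± 1.17 against 20.9 ± 7.41) fell. Crebbp (154 ± 32.4 against 149 ± 5.19 CPM, log2 0.053 ± 0.16), Kat6a (21.1 ± 1.04 against 17.7 ± 1.29 CPM, log2 0.25 ± 0.20) and Kat6b (82.1 ± 27.9 against 115 ± 7.90 CPM, log2 -0.49 ± 0.27) did not pass (edgeR adjusted p = 0.824, 0.356 and 0.174), except Kat6a with library size alone (log2 0.57, 0.0487; range 0.0487 to 0.624).

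Embryos injected with siKat6a were close to siControl. By edgeR 0 genes changed, with 409 at an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. The groups did not overlap for 9.90% of genes. MERVL-int stood at 33.2 ± 12.02 against 28.5 ± 6.36 CPM and Dppa3 at 10006 ± 2981 against 11460 ± 2965 CPM. Of the 24 lists, 2 passed by camera, although 0 of their members did by edgeR, over all genes or adjusted over the list alone. The integrated stress response genes had a median log2 fold change of 0.16 over 39 genes (camera adjusted p = 1.25e-04, or adjusted p = 0.885 with an estimated correlation) and the respiratory chain genes one of -0.19 over 71 genes (camera adjusted p = 5.96e-07, or adjusted p = 0.885 with an estimated correlation). Without siControl 3 the camera adjusted p was 0.0690 for either list, and without siKat6a 3 it was 0.119 for the stress genes (ranges 3.66e-05 to 0.885 and 2.03e-09 to 0.885). The other 22 lists did not pass (camera adjusted p from 0.144 to 0.998), with 0 members changed in any of them. Ep300 (28.6 ± 4.06 against 26.5 ± 3.58 CPM, log2 0.11 ± 0.29), Crebbp (141 ± 15.9 against 149 ± 5.19 CPM, log2 -0.072 ± 0.16) and Kat6b (122 ± 16.02 against 115 ± 7.90 CPM, log2 0.089 ± 0.27) did not pass (edgeR adjusted p = 1 for each).

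Embryos injected with siKat6b differed from siControl at 4 genes by edgeR, with 2002 at an unadjusted p under 0.05, where DESeq2 called 237, limma-voom 10, no filter 758 and a fit of just these groups 60. The groups did not overlap for 17.1% of genes. The antioxidant enzyme gene Mgst3 (20.2 ± 1.95 against 55.9 ± 7.24) and Ndufa10 (81.1 ± 16.9 against 223 ± 5.01), a complex I subunit, fell (edgeR adjusted p = 0.0485 and 0.00576). The others, which rose, lay outside the rule for naming genes. Without siKat6b 2 there were 163 genes, without siKat6b 1 or siKat6b 3 there was 1, and without any siControl library there were 2. Mgst3 missed the threshold without siControl 1 (0.0999), 2 (0.291) or 3 (0.184) and without siKat6b 1 (0.205) or 3 (0.247). It also missed it with a replicate block (0.114), DESeq2 size factors (0.0598), library size alone (0.0635), the filter at 5 CPM (0.0654) and halved counts (0.0544; range 2.02e-07 to 0.295). Ndufa10 missed it without siKat6b 1 (0.0755) or 3 (0.111; range 2.19e-10 to 0.551).

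In the siKat6b libraries MERVL-int stood at 641 ± 523 against 28.5 ± 6.36 CPM (log2 4.49 ± 1.16; edgeR adjusted p = 0.182). It passed without siKat6b 2 (log2 5.05, adjusted p = 0.0302) and with just these groups in the fit (0.0440). By camera, 8 lists passed, although edgeR called 0 of their members, apart from Ndufa10. With the camera adjusted p in parentheses, median log2 fold changes were 2.94 over 32 2-cell genes (1.70e-08), -0.39 over 71 respiratory chain genes (1.25e-17), -0.24 over 77 ribosomal protein genes (2.76e-09) and 0.25 over 39 integrated stress response genes (0.001). They were -0.22 over 43 trophectoderm genes (0.00258), 0.23 over 37 p53 targets (0.00899), 0.54 over 35 neuronal genes (0.0229) and -0.78 over 4 Y-linked genes (0.00899). With an estimated correlation each was lost (adjusted p = 0.497, and 0.596 for the ribosomal list). Adjusted over the list alone, 13 of the 2-cell genes and 2 of the p53 targets were higher and 18 of the respiratory chain genes and 1 of the trophectoderm genes lower. Without siKat6b 1 the camera adjusted p was 0.153 for the p53 targets and the neuronal genes and 0.321 for the Y-linked genes. The neuronal call was also lost without siControl 1 (0.0560), siControl 2 (0.0705) or siKat6b 3 (0.0976). Ranges over alternatives were 8.60e-04 to 0.979 (p53), 0.0147 to 0.979 (neuronal) and 3.16e-04 to 0.979 (Y-linked). The libraries siKat6b 1 and 3, with siP300 2 and siComb 2, stood apart on the second principal component and in MERVL-int. A fit without these 4, chosen after seeing the data, left siKat6b 1 library, picked partly by MERVL-int, and took its spread from other groups. Calls lost in it, which the ranges involving siKat6b include, thus show nothing on siKat6b. The other 16 lists did not pass (camera adjusted p from 0.0874 to 0.948), with 0 members changed; adjusted over the list alone, 1 glycolysis, 1 germline and 1 blood gene were higher and 1 imprinted gene was higher and 1 lower. Ep300 (28.3 ± 2.00 against 26.5 ± 3.58 CPM, log2 0.094 ± 0.29), Crebbp (138 ± 16.4 against 149 ± 5.19 CPM, log2 -0.11 ± 0.16) and Kat6a (17.8 ± 0.385 against 17.7 ± 1.29 CPM, log2 0.0062 ± 0.20) did not pass (edgeR adjusted p = 0.955, 0.893 and 1).

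Embryos of the siComb group had lower ribosomal protein and pluripotency genes and higher glycolysis, imprinted, neuronal and p53 target genes and markers of blood and cumulus cells than siControl. With an estimated correlation 0 of the 11 list calls passed (adjusted p from 0.11 to 0.78). The mitochondrial share was 5.14 ± 0.276%, against 2.27 ± 0.281%. Of the 19182 genes tested, 7035 changed, 3760 higher and 3275 lower, 2948 and 2002 of them by at least 2-fold. The groups did not overlap for 51.5% of genes. With library size alone, the median over all genes moved by 0.26 on the log2 scale and 70.3% of calls were higher, against 53.4%.

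Of the ribosomal protein genes, 74 of 77 fell and 0 rose, median log2 -1.24 (camera adjusted p = 6.35e-27, or adjusted p = 0.251 with an estimated correlation). Under library size alone 70 fell, with a median of -0.98. Rpl26 (712 ± 109 against 2064 ± 336) fell. Of the respiratory chain genes, 35 of 71 fell and 2 rose (37 and 2 adjusted over the list alone), median log2 -0.49 (camera adjusted p = 1.63e-06, or adjusted p = 0.47 with an estimated correlation). With library size alone 20 fell and 4 rose, with a median of -0.23. Atp5k (206 ± 11.7 against 503 ± 103) and Ndufb5 (126 ± 5.70 against 280.5 ± 37.8) fell. Of the glycolysis genes, 16 of 24 rose and 1 fell (18 and 1 adjusted over the list alone), median log2 1.10 (camera adjusted p = 2.73e-06, or adjusted p = 0.11 with an estimated correlation). Among them was Pgk1 (165 ± 3.06 against 20.8 ± 2.54). Of the imprinted genes, 18 of 33 rose and 2 fell, median log2 1.03 (camera adjusted p = 4.54e-04, or adjusted p = 0.154 with an estimated correlation). Among them was Impact (389.6 ± 68.9 against 34.6 ± 2.22). Of the p53 targets, 17 of 37 rose and 2 fell (18 and 2 adjusted over the list alone), median log2 0.55 (camera adjusted p = 2.14e-04, or adjusted p = 0.263 with an estimated correlation). Among them was Mdm2 (472 ± 64.7 against 83.0 ± 2.62).

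Of the neuronal genes, 20 of 35 rose and 1 fell (22 and 4 adjusted over the list alone), median log2 2.45 (camera adjusted p = 3.20e-05, or adjusted p = 0.11 with an estimated correlation). Among them was Bex2 (83.2 ± 38.2 against 2.62 ± 1.65). Of the cumulus and granulosa cell markers, 7 of 11 rose and 0 fell, median log2 2.33 (camera adjusted p = 0.00279, or adjusted p = 0.251 with an estimated correlation). Of the blood and immune cell markers, 4 of 10 rose and 0 fell, median log2 1.32 (camera adjusted p = 0.00274, or adjusted p = 0.154 with an estimated correlation). Among them was Cd68 (59.7 ± 15.0 against 3.78 ± 0.2003). Of the pluripotency and epiblast genes, 17 of 35 fell and 1 rose (19 and 2 adjusted over the list alone), median log2 -0.85 (camera adjusted p = 1.62e-04, or adjusted p = 0.262 with an estimated correlation). Under library size alone 13 fell and 2 rose. Dppa3 (2635 ± 621 against 11460 ± 2965) and Gdf3 (5.28 ± 3.14 against 74.7 ± 13.4) fell. Of the trophectoderm genes, 20 of 43 fell and 6 rose (20 and 7 adjusted over the list alone), median log2 -0.49 (camera adjusted p = 0.0315, or adjusted p = 0.33 with an estimated correlation). With library size alone 14 fell and 9 rose. Id2 (79.6 ± 27.7 against 503 ± 40.2) fell and the claudin gene Cldn6 (174 ± 12.4 against 23.4 ± 4.23) rose.

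Of the 2-cell genes, 20 of 32 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 5.37, or 5.36 with genes at 0 at their bound (camera adjusted p = 0.0311, or adjusted p = 0.78 with an estimated correlation). The call was lost without siComb 2 (camera adjusted p = 0.534) and with library size alone (0.119; range 6.22e-04 to 0.78). MERVL-int (351 ± 503 against 28.5 ± 6.36 CPM, log2 3.63 ± 1.11) rose (edgeR adjusted p = 0.0177). Its call was lost without siControl 1 (0.0647), siControl 3 (0.0653) or siComb 2 (log2 1.09, 0.368), with limma-voom (0.0853) and with a replicate block (0.0539; range 7.77e-58 to 0.368).

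The other 13 lists did not pass with siComb (camera adjusted p from 0.0836 to 0.97). Hmox1 (472 ± 47.8 against 29.3 ± 1.47), the deacetylase gene Hdac1 (362 ± 61.2 against 151 ± 26.9) and Taf7l (96.1 ± 20.5 against 1.796 ± 1.28) rose. Outside the lists, Gpnmb (93.8 ± 33.7 against 0.341 ± 0.422) and Trf (59.7 ± 8.02 against 0.278 ± 0.112) rose.

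Set against the single injections, siComb was nearest to siP300. The groups differed at 150 genes (97 higher and 53 lower in siComb), with 2598 at an unadjusted p under 0.05. The count of 150 was 0 with just these groups in the fit, 35 with limma-voom, 48 with a replicate block, 99 with library size alone, 618 with DESeq2 and 733 with no filter. It was 26 without siComb 1, 42 without siP300 3, 71 without siComb 2 and 79 without siComb 3. The share higher, 64.7%, was 47.5% with library size alone, 43.0% without siComb 3 and 35.7% without siP300 3. The placental growth regulator Phlda2 (305 ± 28.8 against 81.1 ± 36.2) was higher and Laptm5 (6.47 ± 2.16 against 26.8 ± 8.05) was lower (edgeR adjusted p = 0.00583 and 0.00609); with just these groups in the fit the adjusted p was 0.214 and 0.248 (ranges 9.21e-16 to 0.214 and 1.04e-07 to 0.248).

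Between siComb and siP300, Kat6a (11.4 ± 1.29 against 21.1 ± 1.04 CPM, log2 -0.88 ± 0.20) just missed the threshold (95% interval of log2 -1.31 to -0.45, which leaves out 0; edgeR adjusted p = 0.0532). It passed with DESeq2 (0.00356), the filter at 5 CPM (0.0315) and halved counts (0.0385; range 0.00356 to 0.399). The groups were not shown to differ in Kat6b (56.4 ± 25.1 against 82.1 ± 27.9 CPM, log2 -0.54 ± 0.27) (-1.12 to 0.036; 0.409), Ep300 (24.0 ± 8.00 against 19.6 ± 8.43 CPM, log2 0.28 ± 0.29) (-0.32 to 0.89; 0.741), Crebbp (183 ± 8.13 against 154 ± 32.4 CPM, log2 0.25 ± 0.16) (-0.098 to 0.60; 0.555) or MERVL-int (351 ± 503 against 377 ± 424 CPM, log2 -0.10 ± 0.99) (-2.20 to 1.99; 0.980). Of the glycolysis genes, 4 of 24 rose and 0 fell (8 and 0 adjusted over the list alone), median log2 0.47 (camera adjusted p = 2.00e-07, or adjusted p = 0.0733 with an estimated correlation). Of the imprinted genes, 3 of 33 rose and 0 fell (8 and 2 adjusted over the list alone), median log2 0.31 (camera adjusted p = 0.00333, or adjusted p = 0.435 with an estimated correlation). Of the trophectoderm genes, 3 of 43 rose and 1 fell (6 and 1 adjusted over the list alone), median log2 0.11 (camera adjusted p = 0.0226, or adjusted p = 0.549 with an estimated correlation). Of the heat shock genes, 1 of 26 rose and 0 fell (3 and 0 adjusted over the list alone), median log2 0.23 (camera adjusted p = 0.0157, or adjusted p = 0.549 with an estimated correlation). Of the ribosomal protein genes, 0 of 77 passed, median log2 -0.27 (camera adjusted p = 3.08e-05, or adjusted p = 0.735 with an estimated correlation). The other 19 lists did not pass (camera adjusted p from 0.114 to 0.858).

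Against siKat6a, siComb differed at 6901 genes (3674 higher and 3227 lower; 68.4% higher with library size alone, against 53.2%, the median moving by 0.23). Against siKat6b it differed at 6051 (3148 and 2903; 64.0% against 52.0%, the median moving by 0.16). Kat6b (56.4 ± 25.1 against 122 ± 16.02 CPM, log2 -1.12 ± 0.28) was lower than in siKat6a (95% interval -1.70 to -0.54; edgeR adjusted p = 0.00495), while Kat6a (11.4 ± 1.29 against 12.9 ± 1.58 CPM, log2 -0.18 ± 0.20) and Ep300 (24.0 ± 8.00 against 28.6 ± 4.06 CPM, log2 -0.25 ± 0.29) were not shown to differ (-0.61 to 0.25 and -0.86 to 0.35; edgeR adjusted p = 0.521 and 0.516). Crebbp (183 ± 8.13 against 141 ± 15.9 CPM, log2 0.37 ± 0.16) missed the threshold (0.027 to 0.72; edgeR adjusted p = 0.0848) but passed with DESeq2 size factors (0.0468), library size alone (0.0127), DESeq2 (0.0285) and the filter at 5 CPM (0.0237; range 0.0127 to 0.254). Kat6a (11.4 ± 1.29 against 17.8 ± 0.385 CPM, log2 -0.64 ± 0.20) was lower than in siKat6b (-1.07 to -0.21; edgeR adjusted p = 0.0234), but not without siKat6b 2 (0.0528), siKat6b 3 (0.0591) or siComb 2 (0.0858), without a filter on low counts (0.202), with library size alone (0.108) or with just these groups (0.105; range 0.0169 to 0.28). Kat6b (56.4 ± 25.1 against 78.1 ± 6.79 CPM, log2 -0.47 ± 0.27) did not pass (-1.05 to 0.11; edgeR adjusted p = 0.204) except without siComb 3 (log2 -0.86, 0.0248; range 0.0248 to 0.598). Ep300 (24.0 ± 8.00 against 28.3 ± 2.00 CPM, log2 -0.24 ± 0.29) did not pass (-0.85 to 0.37; edgeR adjusted p = 0.562). Crebbp (183 ± 8.13 against 138 ± 16.4 CPM, log2 0.41 ± 0.16) missed the threshold (0.066 to 0.76; edgeR adjusted p = 0.065) but passed with the same alternatives (0.0364, 0.0197, 0.0186 and 0.0245) and with just these groups in the fit (0.0440; range 0.0186 to 0.263).

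MERVL-int (351 ± 503 against 33.2 ± 12.02 CPM, log2 3.40 ± 1.10) was higher in siComb than in siKat6a (95% interval 1.08 to 5.73, edgeR adjusted p = 0.0236), but not without siComb 2 (log2 0.86, 0.482), siKat6a 1 (0.0870), siKat6a 2 (0.0745) or siKat6a 3 (0.0541), nor with limma-voom (0.122) or a replicate block (log2 2.59, 0.0872, range 1.76e-52 to 0.482). Against siKat6b it did not pass (351 ± 503 against 641 ± 523 CPM, log2 -0.87 ± 1.00, 95% interval -2.98 to 1.24, edgeR adjusted p = 0.545) except without siComb 2 (log2 -3.40, 0.0174, range 4.02e-04 to 0.841). In both comparisons the same 8 lists passed, and in brackets are differing counts adjusted over the list alone. Members that rose and fell, against siKat6a then siKat6b, numbered 0 and 71 [0 and 74] then 0 and 71 [0 and 72] of 77 ribosomal protein genes, 15 and 1 [16 and 1] then 14 and 1 [15 and 1] of 24 glycolysis genes, 17 and 1 [19 and 2] then 19 and 2 [19 and 3] of 33 imprinted genes and 1 and 19 [1 and 22] then 0 and 19 [1 and 21] of 35 pluripotency genes. They numbered 20 and 2 then 16 and 2 [17 and 2] of 35 neuronal genes, 15 and 2 then 15 and 2 of 37 p53 targets, 7 and 1 then 6 and 1 of 11 cumulus markers and 5 and 0 then 4 and 0 of 10 blood markers. These camera adjusted p values lay between 2.93e-25 and 0.00961, and the adjusted p between 0.0901 and 0.481 with an estimated correlation. Of the respiratory chain genes, 23 of 71 fell and 3 rose (24 and 3 adjusted over the list alone), median log2 -0.29 (camera adjusted p = 0.00104, or adjusted p = 0.652 with an estimated correlation) against siKat6a. Against siKat6a the other 15 lists did not pass (camera adjusted p from 0.0996 to 0.982), and against siKat6b the other 16 (0.104 to 0.838).

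**Figure D3:**
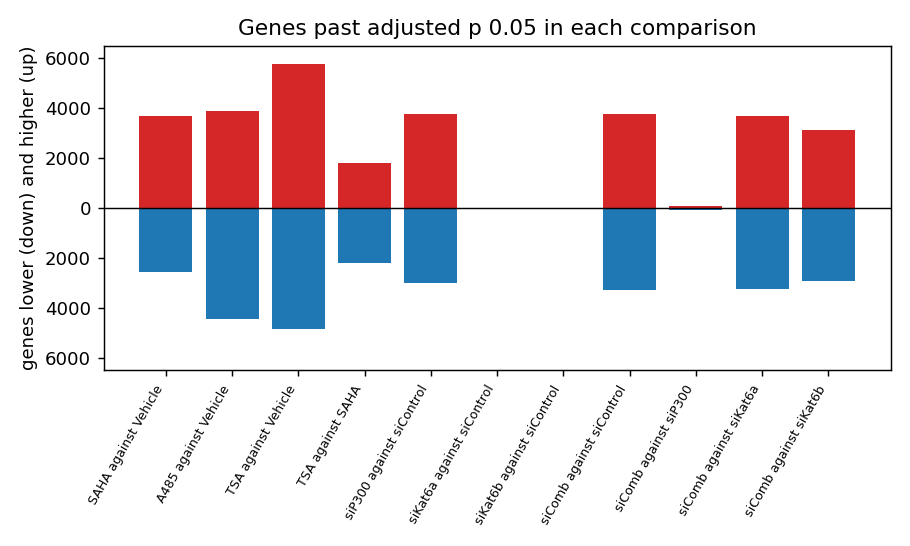
Genes higher (up) and lower (down) in each comparison by edgeR (adjusted p under 0.05). The bars for siKat6a against siControl stand at 0, and those for siKat6b at 2 up and 2 down. Those for siComb against siP300 reach 97 up and 53 down, where TSA against Vehicle reaches 5782 up and 4859 down.

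The siP300 and siComb comparisons shared 5056 changes in the same direction and 4 in opposite directions (742 higher in both, 513 lower in both and 1235 opposite for independent lists). Across 19182 genes their log2 fold changes correlated at r = 0.898 (covariance 2.68). Unchanged groups and a control, all simulated from the siControl mean, gave r = 0.503 and covariance 0.119. The log2 fold changes of siKat6b correlated with those of siP300 at r = 0.587 (covariance 1.10) and of siComb at r = 0.522 (covariance 0.975). For siKat6a, r was 0.234 with siP300 (covariance 0.300), 0.233 with siComb (0.299) and 0.369 with siKat6b (0.297). Part of each excess may come from the shared siControl libraries.

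Between the families, which share no library, A485 and siP300 changed 2936 genes in the same direction and 624 in opposite directions (742, 731 and 1482 for independent lists; r = 0.228 across 17194 genes), and A485 and siComb 3340 and 555 (759, 785 and 1550; r = 0.281). The pairs with SAHA and TSA were chosen after seeing the data. SAHA and siP300 shared 2255 and 357 were opposite (609, 437 and 1033; r = 0.570), and SAHA and siComb 1986 and 530 (623, 469 and 1084; r = 0.473). TSA and siP300 shared 3705 and 450 were opposite (963, 826 and 1785; r = 0.640), and TSA and siComb 3449 and 704 (985, 887 and 1870; r = 0.541).

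The median, the mean and the camera direction differed in sign just for lists that did not pass. With SAHA these were the deacetylase, heat shock, YAP TEAD, cholesterol, respiratory chain, imprinted and Y-linked lists, and with A485 the maternal, acetyltransferase, stress response and imprinted lists. With TSA they were the p53, stress response, heat shock and cumulus lists, and between TSA and SAHA the heat shock and cumulus lists. In siP300 they were the primitive endoderm and heat shock lists, and in siComb the acetyltransferase, heat shock and oviduct lists. In siKat6a they were the maternal, deacetylase, DNA methylation, glycolysis, cumulus, oviduct and blood lists. In siKat6b they were the acetyltransferase, deacetylase, DNA methylation, histone, cholesterol, imprinted and oviduct lists. Between siComb and single injections they were the 2-cell (siP300, siKat6b), histone and oviduct (siP300), and primitive endoderm, stress response and heat shock (siKat6a, siKat6b) lists.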

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

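The tests of scaling and of Vehicle 3 on MERVL-int, the test of genes nearest in length and all counts of splits were chosen after the results they bear on were seen.

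MERVL-int and 2-cell genes were higher with SAHA and TSA and lower with A485. Library size alone moved the median gene by at most 0.085, so 3.17, its smallest log2 fold change in size, does not test scaling. With SAHA and TSA scaling is argued against for the 2-cell list, since it moves all genes alike. There, medians of the 2-cell and ribosomal lists lay at least 5.09 apart, quartiles apart too. The high count in Vehicle 3 is argued against for the rises, since a high control can just shrink a rise (without it log2 8.18, edgeR adjusted p = 3.35e-09, and 9.52). For the falls it may be the source: without Vehicle 3 the MERVL-int log2 with A485 was -0.484, not -3.24 (edgeR adjusted p = 0.324, range 2.92e-74 to 0.324), and 9 of the 33 2-cell genes still fell. Blocked deacetylases and reads shared between MERVL copies stay open, as untested.

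Ribosomal protein genes were lower in siP300 and siComb, with medians of -0.97 and -1.24. Scaling is argued against, since with library size alone the medians were -0.662 and -0.975. A bias by gene length stays open. Other genes within the range of length and CPM of the list had medians of -0.057 in siP300 and -0.041 in siComb, beyond the bound set beforehand for excluding it, but that bound was wrong, since the range took in 10516 of 19182 genes. The 147 genes nearest in length and CPM had medians of -0.607 and -0.506, with 78 and 71 of them lower, so a loss shared by short and abundant transcripts may account for part, and an effect of the injected siRNAs stays open, as untested.

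Many genes changed in siP300 and siComb, with little loss of Ep300 mRNA. Of 20 interferon-induced genes tested, 7 rose in siP300 and 9 in siComb (between the bounds set beforehand) but 0 in siKat6a and siKat6b. This argues against a response to injected RNA as such, and one to particular siRNAs stays open. Across genes the siP300 fold changes correlated with those of A485 at r = 0.228 and TSA at 0.640. The bound set beforehand, a lower value with A485, was met and goes against lower p300 activity. Shared calls do not decide, since TSA changed more genes. The bound was wrong, since lower p300 activity does not forbid a likeness to TSA, so it stays open, with protein not measured.

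Effects against the same control differed by a test of the difference itself at 3983 genes between TSA and SAHA, at 150 between siComb and siP300, at 6901 between siComb and siKat6a and at 6051 between siComb and siKat6b.

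The 6 libraries of a comparison make 10 splits into groups of 3, too few for a share under 0.05. The real split was the 1 of 10 with the highest count for SAHA (6261 genes), A485 (8328), TSA (10641), siP300 (6789), siComb (7035), TSA against SAHA (3983) and siComb against siKat6a (6901), where the highest other split gave 0. It was also 1 of 10 for siKat6b (4 genes, highest other 1), siComb against siP300 (150, highest other 39) and siComb against siKat6b (6051, highest other 4). For siKat6a 10 of 10 splits gave 0 genes by edgeR.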

How the results depend on the processing

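The tests with halved counts, the fit without 4 siRNA libraries that stood apart (siP300 2, siKat6b 1, siKat6b 3, siComb 2) and the overlaps of SAHA and TSA with siP300 and siComb were chosen after seeing the data. That fit leaves siP300 and siComb 2 libraries and siKat6b 1, so calls lost or signs turned in it for siKat6b, whose spread then comes from other groups, show nothing on stability. Counts of changed genes stayed within 1.5-fold for SAHA, A485, TSA, siP300, siComb and siComb against siKat6a under every alternative run, and the series-wide table gave the same counts as the sample files, so that alternative moved nothing. Where a value below crossed a threshold or turned sign, the cause was not tested. Where few genes change, as simulated, 38.8% and 29.9% of 2-fold changes were recovered, so small ones were largely missed there.

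With an estimated correlation, 4 lists passed for SAHA (8 with the preset one), 3 for A485 (7), and 0 for TSA (8), siP300 (12), siKat6a (2), siKat6b (8) and siComb (11). By fry, 13 passed for SAHA, 13 for A485, 17 for TSA, 15 for siP300, 17 for siComb and 0 for siKat6a and siKat6b. Without the 4 libraries (1 of siKat6b left), 2 passed for siKat6b, and its Y-linked list turned sign (camera adjusted p = 0.979). For siKat6a DESeq2 called 1 gene and no filter 15. For siKat6b (4 genes) DESeq2 called 237, limma-voom 10, no filter 758, all 27 libraries 29 and just the groups compared 60, while DESeq2 size factors, a filter at 5 CPM, the replicate block and halved counts each gave 2. TSA against SAHA gave 2442 genes with at least 2-fold change. For siComb against siP300 (150) library size alone gave 99, DESeq2 618, limma-voom 35, no filter 733, the replicate block 48 and just the groups compared 0. For siComb against siKat6b (6051), 3576 were called without the 4 libraries (2 against 1 left).

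At adjusted p under 0.01 in both, calls in the same direction numbered 3575 (SAHA and TSA), 1169 (SAHA and A485), 2185 (A485 and TSA), 2783 (siP300 and siComb), 1598 (A485 and siP300), 1924 (A485 and siComb), 946 (SAHA and siP300), 847 (SAHA and siComb), 1882 (TSA and siP300) and 1832 (TSA and siComb). Signs turned for Kat6a with TSA (0.034) with library size alone (-0.054), no filter (-0.023) and all 27 libraries (-0.031). They turned for Ep300 in siComb (-0.15) with library size alone (0.12) and without the 4 libraries (0.096), for Kat6a in siComb against siKat6a with library size alone (0.057), and for MERVL-int in siComb against siKat6b without the 4 libraries (0.73). None of these passed. The difference in genes with at least 1 count moved by more than its spread with a minimum of 10 counts or after thinning: to 1468 and 2113 for SAHA and 1750 and 2714 for TSA, and with 10 counts to -456.3 for A485, 605.7 for siKat6b and 1355 for siComb.

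Leaving out each library in turn gave 0 to 4 lists for siKat6a and 5 to 9 for siKat6b, and 1 to 163 genes for siKat6b, 2420 to 3359 for TSA against SAHA and 26 to 165 for siComb against siP300. Log2 fold changes that turned sign ran from -0.041 to 0.15 for Kat6a with TSA, -0.12 to 0.20 for Crebbp in siP300, -0.037 to 0.064 for Kat6a in siKat6b, -0.39 to 0.088 for Ep300 in siComb and -2.63 to 1.41 for MERVL-int in siComb against siP300. In siKat6a they ran from -0.16 to 0.0029 for Crebbp, -0.017 to 0.17 for Kat6b, -0.10 to 0.43 for MERVL-int and -0.46 to 0.035 for Dppa3. Over named genes and libraries left out, 1515 values kept sign and side of the threshold, 44 lost the call, 4 gained it and 15 turned sign, and over list calls 318 held and 18 were lost. DESeq2, lacking values for some named-gene results, kept 248 and gained 4, and limma-voom kept 255, lost 6 and gained 2. Library size alone kept 252, lost 4 and gained 4, the fit of just the groups compared kept 250, lost 8 and gained 4, and all 27 libraries kept 261 and lost 1.

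Replicate numbers were not shown to pair the samples. Deviations from the group means correlated above 0.1 for 7 of 18 same-numbered pairs in the inhibitor family (-0.10 to 0.30, median 0.058) and 4 of 30 in the siRNA family (-0.52 to 0.60, median -0.042), over 9294 genes. Best with its own number were 8 of 12 and 1 of 15 libraries. With the number as a replicate block, 255 named-gene results and 56 of 56 list calls stayed and 8 named-gene calls were lost, among them MERVL-int with A485 (log2 -2.44).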

Other observations

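The list of interferon-induced genes held 30 genes and was written before its values were seen. Of 16 tested in the inhibitor family, 7 rose and 0 fell with SAHA (median log2 0.99), 10 rose and 3 fell with TSA (1.04), and 3 rose and 4 fell with A485 (-0.45). Of 20 tested in the siRNA family, 7 rose and 1 fell in siP300 (0.76), 9 rose and 1 fell in siComb (0.75), and 0 changed by edgeR in siKat6a (-0.033) and siKat6b (0.11). Xist, the RNA that coats the inactive X chromosome, stood at 233 ± 79.8 CPM in Vehicle, 88.2 ± 58.5 with SAHA, 77.9 ± 51.2 with A485 and 24.1 ± 14.8 with TSA (two-sided exact permutation p = 0.2, 0.1 and 0.1, where 0.1 is the smallest possible). Y-linked genes together stood at 114 ± 39.3 CPM in Vehicle, 177 ± 55.5 with SAHA, 227 ± 24.4 with A485 and 85.9 ± 52.5 with TSA (exact permutation p = 0.2, 0.1 and 0.5).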
